A study of Mus musculus with 2 samples.

How the data were processed

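PolyA-selected RNA of mouse hearts at embryonic day 12.5 was sequenced in 2 libraries, one per biological replicate. Per the labels, each library came from hearts of male and female embryos of strain B6NCrl pooled together, started from 10 ng of RNA, and was fragmented by Nextera tagmentation. Per the labels, ERCC transcripts (synthetic RNAs of known sequence) were added to each library at 1000 times the amount used for a single cell. The labels give both libraries the same donor identifier and separate biosamples, so p-values here concern these 2 samples only.

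The authors deposited gene and transcript tables of each library on 2 releases of the gene annotation, M21 and M4, both on the mm10 genome build, per the text deposited beside the tables. The deposited expected counts are estimated reads per gene or transcript, in which a read that maps to several places is shared out. They need not be whole numbers, and they were rounded to whole numbers for tests. The deposited TPM values are transcript abundances scaled by effective length to a fixed total over every feature in a table, spike-ins and mitochondrial genes included, per the file headers and the sums of the columns. The deposited FPKM values are fragments scaled by effective length and by the read total, per the file headers. The authors' tables also hold a posterior mean TPM and a posterior standard deviation of each count, which measures how uncertainly reads were assigned between similar loci. The column layout is that of RSEM tables, but the aligner, the counter, their versions and the use of strand are not given in the sources used here. Reads of a gene and of an antisense gene that overlaps it therefore cannot be separated here.

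The M21 table was the main one, because it is the newer annotation. It holds 55536 genes, 96 ERCC rows, 1 phiX row and 26248 rows with numeric identifiers, which the files do not pair with names and which were left out of gene counts. Gene symbols, biotypes and coordinates (mm10, 1-based) came from the matching of gene identifiers to the reference annotation. Of 531 distinct symbols in the gene lists, 530 were matched, and Ahsp was not.

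The 35 gene lists, the 30 pairs of related genes, the 30 genes of the transcript comparison, the tests and the rule for naming genes were written before the data were examined. The rule names 6 kinds of genes. These are the 15 nuclear protein-coding genes with the highest mean TPM, the 3 highest members of each list with up to 2 members under a TPM of 1 in both libraries, and all pairs. They are also, of genes that differed between the libraries, the 10 highest and the 10 lowest ratios with any list member that was called, the 10 genes that differed most between annotations at a TPM of at least 10 in a table, and the 8 lowest and 4 highest shares of a dominant transcript. Unnamed and pseudogene models were counted and not named, and a few genes that the rule names are not reported here. A further 5 lists, a second list each for hepatocytes, megakaryocytes, erythroid cells and lung with a list for visceral yolk sac endoderm, were added after the data were seen.

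The design has a single group, so no conditions were compared. Levels are means ± SD over both libraries (n = 2), and a gene counted as detected at a TPM of at least 1 in both. Shares of counts carry exact Clopper-Pearson 95% intervals, and a share of 0 carries the limit that 3 counts allow. No molecular identifiers were used here, so intervals and floors cover counting error only. A chi-square test of homogeneity over genes with a summed count of at least 10 asked whether the libraries were 1 library deposited more than once. Agreement was measured by Pearson and Spearman correlation of log2(TPM + 1) across genes, which are not independent replicates, and by the biological coefficient of variation of edgeR 4.0.16 from an intercept-only design after its filterByExpr step.

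Genes were compared between the libraries with an exact conditional binomial test, two-sided, on rounded counts scaled by the TMM method of edgeR. Genes with a summed count of at least 20 were tested, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05 with an absolute log2 ratio of at least 1. Ratios are replicate 2 over replicate 1 with 0.5 added to each scaled count, and their 95% intervals are exact. The test covers counting error alone, so it compares those 2 libraries and says nothing of conditions. A fold against a library with no counts was computed against a floor of 3 counts per library. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Within-library ratios of pairs were tested with limma 3.58.1 (intercept-only model, empirical Bayes, 0.5 added to each TPM) over the 30 pairs. Ratios of different genes also carry length and coverage bias that replicates share.

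On simulated counts for 17708 genes with 200 changed, the test between the 2 libraries called 99.0% of 4-fold changes, 59.6% of 2-fold changes and 0.069% of unchanged genes. Every simulated gene had the same coefficient of variation, whereas the real libraries spread more widely at low counts. The share of unchanged genes called may therefore be too low there. A true 2-fold change lies at the fold threshold itself, which limits the share called. On 30 simulated pairs, the limma step called 15 of 15 true ratios and 0 of 15 null ones. The true ratios were all 2-fold and every pair had the same small spread. That result therefore does not cover smaller ratios or more variable pairs. The alternatives tried were DESeq2 1.42.0 size factors, total counts and ERCC totals as scaling, no filter or a summed count of at least 100, the M4 tables, other TPM minimums, pseudocounts and prior counts, FPKM, counts scaled to a fixed total, posterior mean TPM, and each library alone. An edgeR exact test with the dispersion estimated from both libraries was also run. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.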

Results

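Transcript levels were measured in the whole heart of the mouse embryo at day 12.5, when the chambers are formed, the cushions that give rise to the valves are present and embryonic red cells circulate. The 2 libraries are biological replicates of 1 group, embryonic heart. The questions that this design allows are which genes the tissue expressed, how related genes compared within a library, and how far the 2 libraries differed. Expected counts summed to 35520161 in replicate 1 and 32577548 in replicate 2, of which 34248993 and 31394912 lay on genes. ERCC spike-ins, synthetic RNAs added to each library, took 3.60 ± 0.0364% of counts (SD, n = 2). In replicate 1 their share was 3.58% (95% Clopper-Pearson interval 3.57 to 3.58%), and in replicate 2 it was 3.63% (3.62 to 3.64%). No count fell on phiX, which allows a share of up to 8.45e-06% in replicate 1 and 9.21e-06% in replicate 2.

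Globin transcripts, the messages of the oxygen carrier of red cells, took 2.36 ± 0.197% of counts, with 2.503% (2.498 to 2.508%) in replicate 1 and 2.22% (2.22 to 2.23%) in replicate 2. The mitochondrial genome took 2.02 ± 0.013% and ribosomal protein genes took 1.65%. Protein-coding genes held 92.0% of counts. The 10 most abundant genes held 6.59% of counts and the 100 most abundant held 19.96%. The globin share differed between the libraries by more than its counting interval in each.

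Of 55536 annotated genes, 14246 were detected in both libraries at a TPM (a transcript abundance scaled by length and library total) of at least 1, and 12468 of these were protein coding. A further 1253 genes reached a TPM of 1 in a single library. A TPM of at least 100 was reached in both libraries by 1432 genes, and a TPM of at least 1000 by 109.

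The most abundant messages of nuclear protein-coding genes came from red cells and from the contractile apparatus. Hbb-y (ENSMUSG00000052187, chromosome 7, 103851749 to 103853216 on mm10), an embryonic beta-type globin, stood at 25868 ± 2168 TPM (SD, n = 2). Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298) stood at 20723 ± 1499 TPM and Hba-a1 (chromosome 11, 32283511 to 32284465) at 9526 ± 707.8 TPM. These 2 alpha globin genes are near-identical, so the split of reads between them is uncertain. Actc1 (ENSMUSG00000068614, chromosome 2, 114047282 to 114053548), the alpha-actin of heart muscle, followed at 9388 ± 77.2 TPM. Myl2 (ENSMUSG00000013936, chromosome 5, 122100951 to 122113472), the regulatory light chain of ventricular myosin, stood at 5779.9 ± 246.3 TPM, and Myl7 (chromosome 11, 5896637 to 5898782), its atrial counterpart, at 4479 ± 244.2 TPM. Nppa (chromosome 4, 148000722 to 148002079), which encodes atrial natriuretic peptide, stood at 4542 ± 126.5 TPM. Myh7 (chromosome 14, 54970684 to 54994626), the beta-myosin heavy chain, stood at 4496 ± 176.7 TPM, and Tnnt2 (chromosome 1, 135836354 to 135852260), cardiac troponin T, at 4219 ± 78.1 TPM. The others of the 15 highest of this class were Actb, Hba-x, Atp5b, Tpm1, Ppia and Gapdh, between 3405 ± 31.2 TPM (Gapdh, a glycolytic enzyme) and 4948 ± 30.9 TPM (Actb, a cytoskeletal actin).

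The 35 gene lists asked which programmes and cell types the tissue held. Of 577 list entries, 517 reached a TPM of 1 in both libraries, and 18 lists had every measured member there. All 30 genes of the sarcomere and contractile apparatus were detected, with a median of 843 ± 9.98 TPM (SD, n = 2). Their summed level was 53152 ± 301.9 TPM. Cardiac transcription factors were detected for 28 of 30 genes at a median of 20.95 ± 0.605 TPM. Nkx2-5, an early cardiac homeobox factor, stood highest at 161 ± 5.72 TPM, followed by Gata4 at 153 ± 5.47 TPM and Mef2c at 95.5 ± 5.06 TPM. Tbx1, a factor of the anterior second heart field, and Foxh1, a partner of Nodal signalling, stayed under 1 in both libraries, at 0.310 ± 0.297 and 0.210 ± 0.198 TPM.

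**Figure D1:**
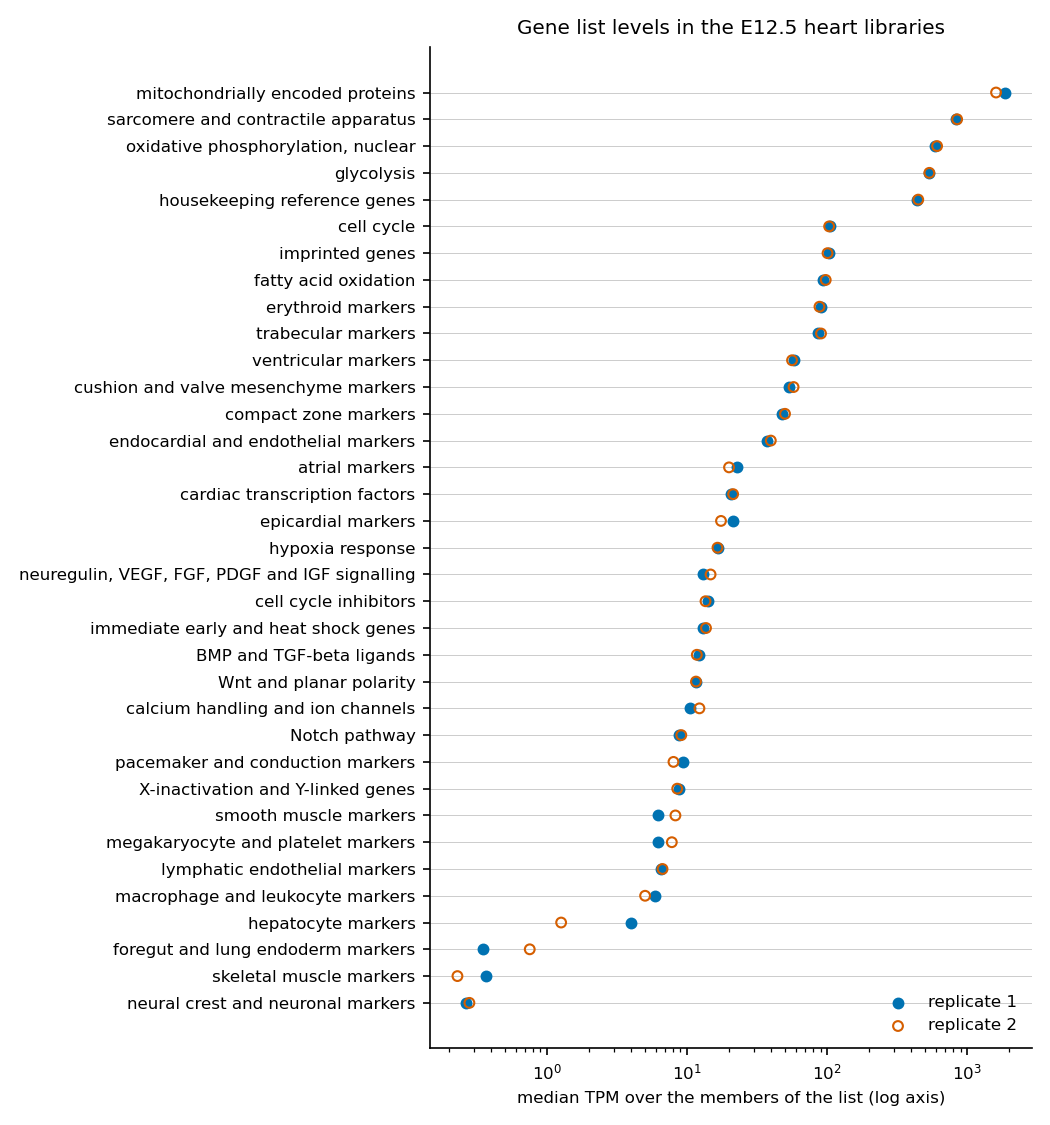
Median TPM of each gene list in each library on a log axis, with a point per library. The mitochondrially encoded proteins and the sarcomere lie highest and the neural crest, skeletal muscle and foregut lists lowest.

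Markers of both chamber types were abundant. All 12 atrial markers and all 12 ventricular markers were detected, at medians of 21.4 ± 1.92 and 57.4 ± 1.58 TPM. Myl4, the atrial essential light chain, stood at 1932 ± 9.23 TPM and Myl3, its ventricular counterpart, at 2752 ± 86.3 TPM. All 8 trabecular markers were detected (median 88.6 ± 2.93 TPM). Among them were Cited1, a transcriptional cofactor, at 767 ± 54.0 TPM and Nppb, a natriuretic peptide gene, at 218 ± 2.49 TPM. The 6 compact zone markers had a median of 49.1 ± 1.56 TPM, with Hspb7 at 154 ± 12.9, Tbx20 at 84.0 ± 3.67 and Mycn, a growth regulator, at 58.8 ± 0.113 TPM. Pacemaker and conduction markers were detected for 13 of 15 genes at a median of 8.70 ± 0.955 TPM. The gap junction genes Gja5 (117 ± 0.962 TPM) and Gjc1 (55.4 ± 1.40 TPM) led them, then Bmp4. Cntn2, an adhesion molecule of conduction cells, stayed under 1.

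Markers listed for cells other than heart muscle were also detected, but levels in whole tissue do not show which cells expressed them. All 20 endocardial and endothelial markers were detected at a median of 38.6 ± 1.63 TPM, with Plvap at 151 ± 8.90, Eng at 128 ± 4.91 and Egfl7 at 111 ± 3.90 TPM. The 13 epicardial markers had a median of 19.4 ± 2.65 TPM, with Krt19, Tcf21 and Upk3b highest at 68.2 ± 0.389, 59.0 ± 1.39 and 47.1 ± 0.049 TPM. The 19 cushion and valve mesenchyme markers had a median of 55.9 ± 2.67 TPM. The matrix genes Col3a1 (535 ± 5.66 TPM), Fn1 (336 ± 16.4 TPM) and Col1a1 (332 ± 24.4 TPM) led them. Smooth muscle markers passed for 8 of 9 genes at a median of 7.26 ± 1.45 TPM, with Acta2 at 826 ± 38.9 TPM, Cnn1 at 317 ± 15.2 TPM and Tagln at 191 ± 10.3 TPM. The other, Myh11, the smooth muscle myosin gene, stood at 0.58 TPM in replicate 1 and 1.37 TPM in replicate 2. All 17 measured erythroid markers were detected at a median of 89.7 ± 1.85 TPM. Macrophage and leukocyte markers passed for 14 of 16 genes at a median of 5.46 ± 0.612 TPM. Lyz2, C1qb and Fcer1g were highest in that list, while Ptprc and Fcgr1 stayed under 1. All 8 megakaryocyte and platelet markers passed at a median of 6.998 ± 1.14 TPM, with Pf4, a platelet chemokine, at 64.7 ± 8.39 TPM, Itga2b at 15.2 ± 3.25 TPM and Ppbp at 13.3 ± 3.97 TPM. Lymphatic endothelial markers passed for 4 of 5 genes (median 6.61 ± 0.134 TPM), led by Pdpn, Prox1 and Flt4, with Ccl21a under 1.

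Lists of neighbouring or foreign tissues stood low. Neural crest and neuronal markers passed for 5 of 14 genes at a median of 0.272 ± 0.011 TPM, although Ednrb, an endothelin receptor, stood at 97.3 ± 5.12 TPM. Tubb3 came next at 6.53 ± 0.849 TPM, and Sox10 stayed under 1. Skeletal muscle markers passed for 5 of 15 genes with medians of 0.37 TPM in replicate 1 and 0.23 TPM in replicate 2. Tnnt1 (426.7 ± 5.18 TPM), Ckm (48.0 ± 0.771 TPM) and Tnni2 (40.7 ± 1.435 TPM) were the highest of them, while the myogenic regulators Myod1 and Myf5 stayed under 1. Foregut and lung endoderm markers passed for 3 of 12 genes (median 0.552 ± 0.286 TPM, with 0.35 in replicate 1 and 0.755 in replicate 2). Id2 stood at 341 ± 2.97 TPM, then Epcam at 2.63 ± 0.552 and Cldn6 at 2.09 ± 0.488 TPM, with Foxa1 and Sftpc under 1. Hepatocyte markers passed for 8 of 14 genes at a median of 2.61 ± 1.91 TPM, with 3.96 in replicate 1 and 1.26 in replicate 2. Their summed level was 266.1 TPM in replicate 1 and 71.97 TPM in replicate 2, with Afp, Trf and Apoa2 the most abundant.

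Energy metabolism and growth programmes were broadly expressed. The 21 glycolysis genes had a median of 535 ± 4.31 TPM, with Gapdh, Ldha (2248 ± 14.4 TPM) and Eno1 (1684 ± 23.6 TPM) highest. The 30 nuclear genes of oxidative phosphorylation had a median of 603 ± 11.3 TPM, led by Atp5b, Cox8a and Atp5g3. Mitochondrially encoded proteins had a median of 1734 ± 173 TPM over 13 genes, led by mt-Atp6, mt-Atp8 and mt-Cytb. The genes mt-Atp6 and mt-Atp8 overlap, so their split is uncertain. Fatty acid oxidation genes passed for 21 of 22 genes at a median of 95.9 ± 2.96 TPM. Fabp3, a fatty acid carrier, stood at 607 ± 20.4 TPM, then Acadl and Hadhb, with Ucp3 under 1. Calcium handling and ion channel genes passed for 30 of 35 genes at a median of 11.4 ± 1.20 TPM. Pln, the regulator of the calcium pump, stood at 537 ± 21.8 TPM, the pump gene Atp2a2 at 327 ± 6.83 TPM and the connexin gene Gja1 at 267 ± 7.74 TPM. Scn4b, a sodium channel subunit gene, stayed under 1. All 28 cell cycle genes passed (median 104 ± 0.785 TPM), with Ccnd2 at 515 ± 8.61, Ccnd3 at 418 ± 1.27 and Hmgb2 at 273 ± 3.48 TPM. Cell cycle inhibitors passed for 8 of 9 genes (median 13.9 ± 0.403 TPM). Cdkn1c stood at 1004 ± 71.4 TPM, then Cdkn2d and Meis1, while Cdkn2a was listed at 0 in both libraries.

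Signalling genes were mostly at moderate levels. All 20 imprinted genes passed (median 102 ± 1.95 TPM), led by Mest at 2797 ± 165 TPM, Igf2 at 1042 ± 17.9 TPM and Cdkn1c. All 16 Notch pathway genes passed (median 8.97 ± 0.219 TPM), led by Hey2, Hes1 and Rbpj. BMP and TGF-beta ligands passed for 10 of 12 genes (median 12.0 ± 0.279 TPM). Tgfb2, Bmp7 and Bmp4 were the highest of these ligands, and Nodal and Gdf3 stayed under 1. The list of neuregulin, VEGF, FGF, PDGF and IGF signalling passed for 19 of 22 genes (median 13.9 ± 1.23 TPM), led by Igf2, Vegfb and Erbb2, with Fgf10 and Fgf16 under 1. Wnt and planar polarity genes passed for 15 of 16 genes (median 11.6 ± 0.028 TPM), led by Sfrp1, Wnt5a and Fzd2. Immediate early and heat shock genes passed for 15 of 18 genes (median 13.4 ± 0.428 TPM), led by Hspe1, Jun and Ier2, with Fosb and Egr2 under 1. All 18 hypoxia response genes passed (median 16.5 ± 0.004 TPM), led by Ldha, Slc2a1 and Bnip3. Genes of X-inactivation and the Y chromosome passed for 6 of 7 genes (median 8.69 ± 0.219 TPM). Both Xist (11.2 ± 2.10 TPM) and the Y-linked Eif2s3y (26.9 ± 1.69 TPM) and Ddx3y (15.7 ± 0.827 TPM) were present in these pools of both sexes, and Zfy1 stayed under 1. The 14 housekeeping genes had a median of 444 ± 7.12 TPM, led by Actb, Ppia and Eef1a1.

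Within each library, fetal and adult-type isoforms of muscle and metabolic genes were set against each other. Myh7, the slow beta-myosin, exceeded Myh6, the alpha-myosin, by a log2 ratio of 1.04 ± 0.06 (SE, n = 2). That ratio was larger on M4, where replicates 1 and 2 had 3053 and 3217 TPM for Myh7 and 1141 and 1041 TPM for Myh6. Tnni1, the slow skeletal troponin I of the fetal heart, exceeded Tnni3, the cardiac form, by 0.85 ± 0.03. Actc1 exceeded the skeletal actin gene Acta1 by 4.64 ± 0.02 and the smooth muscle actin gene Acta2 by 3.51 ± 0.04. The ventricular light chains exceeded the atrial ones, with Myl7/Myl2 at -0.37 ± 0.07 and Myl4/Myl3 at -0.51 ± 0.03. Cpt1b, the muscle form of the enzyme that admits fatty acids to mitochondria, exceeded the liver form Cpt1a, with Cpt1a/Cpt1b at -2.65 ± 0.04.

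In glucose metabolism, Slc2a1 exceeded the insulin-responsive transporter gene Slc2a4 by 3.57 ± 0.05 on the log2 scale, Hk1 exceeded Hk2 by 2.63 ± 0.04, and Ldha exceeded Ldhb by 1.89 ± 0.02. Eno1 exceeded the muscle enolase gene Eno3 by 3.17 ± 0.03, Pfkl exceeded Pfkm by 1.45 ± 0.03, and Pgam1 exceeded Pgam2 by 0.29 ± 0.04. Ckb exceeded Ckm, the creatine kinase of adult muscle, by 2.57 ± 0.02. Ubiquitous subunits of cytochrome oxidase exceeded their heart and muscle forms, by 1.04 ± 0.03 for Cox6a1/Cox6a2, 2.05 ± 0.02 for Cox7a2/Cox7a1 and 4.45 ± 0.05 for Cox8a/Cox8b. Among the globins, Hbb-y exceeded the adult-type Hbb-bt by 3.35 ± 0.02, whereas Hbb-bh1/Hbb-bt stood at -0.59 ± 0.03 and Hba-x/Hba-a1 at -1.01 ± 0.03. Hbb-bt and Hba-a1 each have a near-identical neighbour, so these 3 ratios are uncertain.

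**Figure D2:**
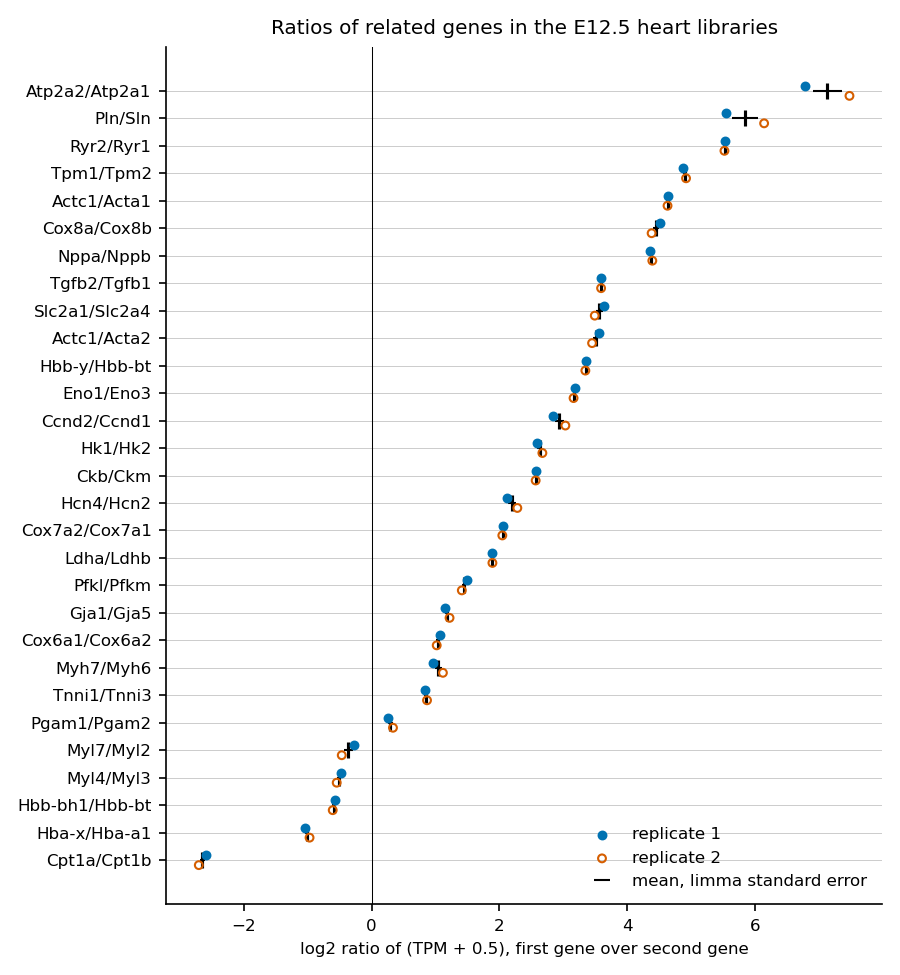
Log2 ratio of TPM within each library for 29 pairs of related genes, with a point per library and the mean with its standard error from limma. All 29 means differ from 0 and 5 of them lie below it; the size of Hcn4/Hcn2 rests on the pseudocount.

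The other pairs given here had the first gene higher. Log2 ratios were 4.90 for Tpm1/Tpm2, 4.38 for Nppa/Nppb, 7.13 for Atp2a2/Atp2a1, 5.53 for Ryr2/Ryr1 and 5.84 for Pln/Sln. They were 1.18 for Gja1/Gja5, 2.94 for Ccnd2/Ccnd1 and 3.59 for Tgfb2/Tgfb1. On the M4 annotation log2 ratios were lower for Ccnd2/Ccnd1 (0.75), Pln/Sln (4.17), Ryr2/Ryr1 (4.74) and Cox7a2/Cox7a1 (1.41). Counts not divided by length gave 8.21 for Atp2a2/Atp2a1, 5.197 for Cox8a/Cox8b, 2.66 for Cox7a2/Cox7a1, 1.46 for Pgam1/Pgam2, 6.49 for Pln/Sln, 6.91 for Ryr2/Ryr1 and 4.38 for Tgfb2/Tgfb1. Ryr1 stood near 0, so Ryr2/Ryr1 also ran from 4.72 to 6.90 with the pseudocount. Hcn4 exceeded Hcn2, which had 2 counts in replicate 1 and 0 in replicate 2, so the size of that ratio rests on the pseudocount and is left out. All 30 pairs passed limma's test, 25 with the first gene higher and 5 with the second, and the largest Benjamini-Hochberg adjusted p was 0.0258 (limma, Myl7/Myl2). The spread was pooled across pairs, and 2 libraries set it.

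The 2 libraries had nearly the same profile. Across 28703 genes Pearson's r of log2(TPM + 1) was 0.993 and Spearman's rho was 0.938; genes are not independent replicates, so no p-value is given. The biological coefficient of variation estimated by edgeR was 4.56% over 17160 genes. Of 13882 genes with a summed count of at least 100, 88.7% had an absolute log2 ratio under 0.25. The chi-square statistic over 20136 genes was 80751 on 20135 degrees of freedom, 4.01 per degree of freedom. The libraries thus differed by more than the sampling of reads, so they are not 1 library deposited more than once. The test cannot tell separate samples from separate libraries of 1 sample. They were counted as 2 samples because the labels give separate biosamples.

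Of the 35 lists, hepatocyte markers, genes of liver secretory proteins, had the median furthest from 0 between the libraries, and they were lower in replicate 2. Afp, which encodes the fetal serum protein alpha-fetoprotein, had 97.49 TPM in replicate 1 and 18.1 TPM in replicate 2, a log2 ratio of -2.46 (95% interval -2.58 to -2.36). Alb, which encodes albumin, had a log2 ratio of -2.33 (-2.71 to -1.99), and Apoa2, an apolipoprotein gene, had -2.09 (-2.48 to -1.74). Of 14 hepatocyte markers, 13 were called lower in replicate 2, and the same number were called when adjusted over the list alone. The others called were Rbp4, Apoa1, Ttr, Apob, Trf, the fibrinogen genes Fga, Fgb and Fgg, and the protease inhibitor genes Serpina1a and Serpina1b, with log2 ratios between -1.23 (Trf) and -3.26 (Fgg). Ahsg had a log2 ratio of -0.91, short of the fold threshold.

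Of 17970 genes tested, 259 differed between the libraries, 116 higher and 143 lower in replicate 2, by the exact binomial test with Benjamini-Hochberg adjustment. The test covers counting error and compares those libraries, not the conditions. By that test without the fold threshold, 1732 genes passed. Of the 259, 117 were unnamed or pseudogene models, and 102 of the 142 named genes were lower in replicate 2. The 10 lowest ratios of named genes included Serpina6, which encodes corticosteroid-binding globulin, with counts of 417 and 41 and a log2 ratio of -3.21 (-3.73 to -2.76), and F12, a coagulation factor gene, with counts of 26 and 2 and -3.30 (-6.70 to -1.58). Pou3f2 had 19 counts against 1, with -3.60 (-9.50 to -1.47). Prss50 had 21 counts against 0, which is 6.44-fold lower in replicate 2 when a floor of 3 counts stands in for 0. That fold is not a bound, and the exact 95% upper limit on the log2 ratio was -2.26, a smaller fold. The values of Rsc1a1, C1s1, Stfa1 and Duxbl2, which were also among the 10 lowest, are uncertain because the authors' posterior standard deviation exceeded 20% of the count in a library.

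Named genes with the 10 highest ratios had fewer than 100 counts in replicate 1, and unnamed models had larger ratios in both directions. Hoxb5, a homeobox gene, had 5 counts in replicate 1 and 61 in replicate 2, a log2 ratio of 3.60 (2.43 to 5.40). Nkx2-1, a transcription factor of lung and thyroid, had 5 and 49 counts, 3.28 (2.09 to 5.10). Foxf1, a factor of visceral mesoderm, had 30 and 149 counts, 2.41 (1.86 to 3.05), and Fendrr, a long non-coding RNA gene beside it, had 2 and 22 counts, 3.28 (1.56 to 6.71). Mal2, an epithelial trafficking gene, had 16 and 72 counts, 2.25 (1.49 to 3.17). Myh11, the smooth muscle myosin gene, had 90 and 196 counts, 1.24 (0.88 to 1.62). Cngb1, Ms4a7 and Casr were called at 4, 4 and 3 counts in replicate 1 and 18, 19 and 17 in replicate 2. All 3 lost the call under the edgeR exact test, whose dispersion was estimated from the same 2 libraries that it compares. The values of Duxbl3, Hist1h2an and mt-Nd4l are uncertain from shared reads. With genes whose posterior standard deviation exceeded 20% left out, 162 genes were called, with a summed count of at least 100 there were 60, and with the edgeR exact test there were 159.

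Medians of 12 of the 35 lists lay outside the central 95% of matched random lists, 7 above and 5 below. Chance would give 1.75 were the lists, and the genes within each list, independent. Many lists share members, and genes of a list can vary together, which random lists leave out. The random range may thus be too narrow and 1.75 too low. The hepatocyte list lay lowest, with a median log2 ratio of -2.21, below all 10000 random medians (central 95% -0.14 to 0.14). All 17 erythroid markers were lower in replicate 2, with a median of -0.18 and none past the fold threshold. Of 12 atrial markers 11 were lower (median -0.14), while 11 of 12 ventricular markers were higher (median 0.06). Sln, an atrial regulator of the calcium pump chosen after its values were seen, stood at -0.57 and Myl7 at -0.14, and Myl2 and Myh7 at 0.06 and 0.05. The Y-linked and X-inactivation list (-0.12) and nuclear oxidative phosphorylation (-0.03) also lay below the random range. In the former the Y-linked Eif2s3y and Ddx3y stood at -0.32 and -0.22, while Xist, of X-inactivation, stood at 0.36. Of its 6 tested members 2 were higher and 4 lower. Its median thus mixes different kinds of genes and does not measure the shift of either kind. Without the fold threshold 4 of these 6 members passed the test between the libraries.

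All 8 megakaryocyte and platelet markers were higher in replicate 2, with a median of 0.38 and no member past the fold threshold. Ppbp stood at 0.59, Itga2b at 0.41 and Pf4 at 0.28. The foregut and lung list had a median of 0.51 over 9 genes, 5 higher and 4 lower, and it stood at -0.0047 over members with a summed count of at least 100. Smaller upward medians were found for trabecular markers (0.07), endocardial and endothelial markers (0.06), cardiac transcription factors (0.05) and the list of neuregulin, VEGF, FGF, PDGF and IGF signalling (0.06). The other 23 medians lay within the random range, between -0.07 (macrophage and leukocyte markers) and 0.08 (cell cycle inhibitors). Over all 551 tested list entries, 16 were called over all genes, in 4 lists, and 17 when adjusted over the list alone. The added one was Tbx1, named after its values were seen.

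**Figure D3:**
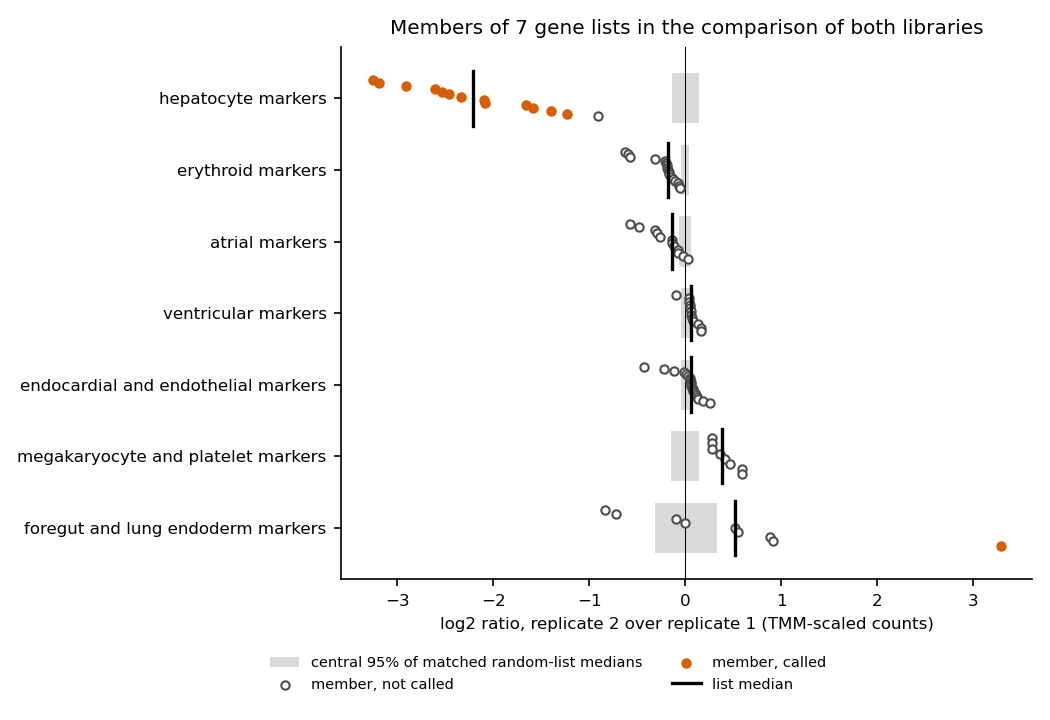
Log2 ratio of scaled counts, replicate 2 over replicate 1, for each tested member of 7 of the 12 lists outside the random range, with the list median as a bar. The grey band is the central 95% of medians of matched random lists, and hepatocyte markers lie lowest with a median of -2.21.

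The most abundant transcript of each of 30 genes was the same in both libraries for all 30, and it held at least 50% of the gene's TPM for 16. Tcap and Nppa, each with a single annotated transcript, stood at 100%, and Actc1 and Nkx2-5 at 99.98 and 99.2%. The lowest shares belonged to Mef2c (25.2 ± 4.71%, SD, n = 2), Tead1 (32.2 ± 1.87%), Fxr1 (35.9 ± 0.507%), Camk2d (36.1 ± 0.021%) and H19 (36.2 ± 0.992%), then Mbnl1, Vcan and Igf2 (37.4, 40.4 and 40.6%). For 3 of the 30 genes the leading model was non-coding: H19, a retained-intron transcript of Tead1 and a processed transcript of Cacna1c at 70.8%, a gene named after its values were seen. On M4 the leading share was 60.9% for Mef2c, with another transcript, and 54.1% for Fxr1. As shares of counts, which are not divided by length, the values were 6.87% for Mef2c, 7.84% for Tead1, 16.8% for Igf2, 68.1% for Vcan and 19.5% for Cacna1c. On the M4 annotation 23 of the 30 genes kept the same leading transcript.

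The annotation itself moved some genes. Of 13828 genes compared between M21 and M4 in the same libraries, 392 (2.84%) differed at least 2-fold in the same direction in both, 249 higher and 143 lower on M21. Ptp4a1, a phosphatase gene, stood at 2.31 ± 0.849 TPM on M21 and 199.8 ± 3.44 TPM on M4, and Usp50 at 2.25 ± 0.099 and 192 ± 9.98 TPM. Nupl1, Pagr1b and Mir8112 were listed at 0 on M21 and at 34.8, 24.0 and 16.1 TPM on M4, and Cfap43 and Ece2 were also lower on M21. Ulk4 (81.4 ± 7.27 TPM on M21, log2 ratio 5.37), Platr25 and Chd9 were higher on M21. Of the list members compared whose levels are given above, 5 moved more than 1.5 times: in replicate 1 and replicate 2 on M4, Actb stood at 2211 and 2277 TPM, Ccnd2 at 112 and 119.6 TPM, Mef2c at 38.7 and 41.0 TPM, Cnn1 at 182 and 184 TPM and Upk3b at 74.0 and 73.3 TPM. Among heart genes, log2 ratios of M21 over M4 were 2.28 for Trdn, 2.15 for Ccnd2, 1.25 for Mef2c, 1.00 for Myh6 and -1.51 for Sln, which were named after their values were seen. Both tables come from the same reads, so these are differences of processing and have no replicated test.

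The spike-ins tracked the endogenous scaling. Of 96 ERCC transcripts, 85 had at least 1 count in replicate 1 and 85 in replicate 2, with 81 in both. Their total had a log2 ratio of 0.02 after TMM scaling, and the median over 64 tested spike-ins was 0.02.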

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

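The test of blood of every kind was chosen only after its result was seen, and no prediction was written for the second erythroid list. The other tests were written before their results were seen. Those on the other second lists and the yolk sac list were written before the values of these lists were looked at. A further condition, that an exact interval of a list's median must clear a bound before an explanation is set aside, was added after the values were seen and can only weaken a verdict. The design has a single group, so no biological difference between groups was tested for any of the 3 patterns; the explanations tested are other cells or their RNA in a library, and the assignment of reads.

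Rows with numeric identifiers, which the gene comparisons leave out, held 41 estimated reads in replicate 1 and 38 in replicate 2, above the 3 reads that a count of 0 allows. The reads lay in 6 of 26248 such rows, and 1 row held 29 and 30 of them. The files do not pair these identifiers with names, so what they measure is not given in the sources used here.

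Hepatocyte markers were lower in replicate 2 (median log2 ratio -2.21, 14 of 14 lower). Reads shared between paralogs are argued against, and 14 of 14 members differed by more than 3 combined posterior standard deviations. For Afp, Alb, Apoa1, Apoa2, Apob, Rbp4, Ttr, Fga, Fgb and Fgg that deviation was 0 in both libraries, so they could not fail this rule. A deviation of 0 leaves no uncertainty in the assignment of their reads. Trf, Serpina1a and Serpina1b had deviations above 0 and also passed. Hepatic cells or hepatic RNA in the replicate 1 library may contribute and stay open. A second hepatocyte list had a median of -0.94, below all random medians but short of the bound of -1 set for it. In that list 12 of 14 tested genes were lower, with 7 called lower and 0 called higher. Its most abundant genes in replicate 1 were Apoc2 (4.25 TPM against 1.24) and Itih2 (3.50 TPM against 0.41), 5 of its 22 genes reached a TPM of 1 in both libraries, and none is in another list. Visceral yolk sac endoderm also stays open, since its list had a median of 0.116 (4 of 6 higher, percentile 78.35), above the bound of -0.5 set against it, but the interval of -2.10 to 0.45 reaches past that bound; the list was led by Rhox5 (10.1 against 8.69 TPM), with 3 of 7 genes at a TPM of 1 in both and none in another list.

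Megakaryocyte and platelet markers were higher in replicate 2 (median 0.38, 8 of 8 higher). More blood of every kind is argued against only if the hepatic material left open above did not shift erythroid genes, which was not tested. The erythroid list had a median of -0.18 with 17 of 17 lower, and a second erythroid list had -0.22 with 10 of 10 lower. More megakaryocytes or platelets in the replicate 2 library stays a hypothesis. A second list passed the bound set for it, with a median of 0.30, 7 of 8 higher and percentile 99.8. The interval of its median runs from -0.11 to 1.42, so no shift is also possible. More markers of the same cells cannot tell the number of cells from the expression per cell. The most abundant genes of this second list were Clec1b (5.20 against 5.77 TPM) and Plek (4.68 against 5.86 TPM). In it 7 of 8 genes reached a TPM of 1 in both libraries, and none is in another list. A difference between embryos was not tested.

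Of the genes called between the libraries, 239 belong to no hepatocyte list. Reads assigned differently among near-identical loci may explain part of them: 38.5% (92 genes, 95% interval 32.3 to 45.0%) had a posterior standard deviation above 20% of the count in a library, against 7.81% of genes not called at the same abundance, under the bound of 50% set for it. A called gene often has few counts in a library, where that mark is easily passed, so part of this contrast is built in. Lung or foregut tissue in the replicate 2 library stays open too, since a second lung list had a median of 0.41 (6 of 9 higher, percentile 99.35, interval -0.10 to 0.91), short of its bound of 0.5. That list was led by Irx2 (11.96 against 12.06 TPM) and Foxp2 (11.4 against 11.05 TPM), with 4 of its 10 genes at a TPM of 1 in both libraries and none in another list. Over members of the first foregut and lung list with a summed count of at least 100 the median was -0.0047, so it depends on which members are kept. The filter drops Nkx2-1, which was called higher in replicate 2, and Foxa1 (8 and 14 counts). Sftpc (0 and 14 counts) was too scarce to be tested at all. Without the filter 5 of 9 tested members were higher and 4 lower. Epcam (79 and 104 counts, log2 ratio 0.51) and Cldn6 (54 and 73 counts, 0.55) pass that filter, while Id2 stood at -0.0067.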

How the results depend on the processing

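The recount without genes of high posterior standard deviation, the total without spike-in rows and the random background without called hepatocyte genes were chosen after seeing the data. With TPM as the unit, shares were 7.74% for ERCC, 3.81% for the mitochondrial genome, 6.73% for globins, 10.6% and 29.6% for the 10 and 100 most abundant genes, 4.15% for ribosomal proteins and 83.2% for protein-coding genes; TPM divides by length, so short transcripts weigh more. On M4, shares were 3.69% for ERCC, 2.04% for the mitochondrial genome, 6.38% for the 10 most abundant genes and 92.4% for protein-coding genes, and the cause was not tested. The coefficient of variation was 4.72% with no filter, 4.53% at a summed count of at least 100 and 4.45% on M4. Pearson's r was 0.974 at a pseudocount of 0.1 and 0.996 at a summed count of at least 100, and Spearman's rho was 0.959 on M4 and 0.996 at that count; the stricter filter drops noisy genes, and otherwise the cause was not tested. Genes differing numbered 60 at a summed count of at least 100, where fewer are tested, 159 with the edgeR exact test, which adds a dispersion, and 162 without genes of high posterior standard deviation, while 6 other alternatives gave 230 to 311. Cngb1, Ms4a7 and Casr lost their calls with the edgeR exact test alone, and 271 other comparisons of named differing genes kept direction and call. Named genes that an alternative's filter dropped, such as Prss50 at a summed count of at least 100, were not compared there. Of the 259 genes of the main call, 192 were also called on M4. The foregut and lung list turned to -0.0047 at a summed count of at least 100, where members at low counts leave; the other 82 comparisons of lists kept their direction, and the hepatocyte median ran from -2.33 to -2.21. All 30 pairs passed limma under 5 alternatives. Genes detected ran from 10625 to 16128, list entries detected from 444 to 525, annotation differences from 302 to 465 and transcripts holding at least 50% from 16 to 22. Leaving out each library gave ranges of 3.58 to 3.63% for ERCC, 2.01 to 2.03% for the mitochondrial genome, 2.22 to 2.503% for globins, 6.575 to 6.61% and 19.9 to 20.05% for the 10 and 100 most abundant genes, 1.63 to 1.67% for ribosomal proteins, 91.9 to 92.1% for protein-coding genes, 14831 to 14914 for genes detected, 521 to 525 for list entries, 457 to 465 for annotation differences and 17 to 17 for transcripts. It is not possible for differing genes, list differences or agreement, which need both libraries, and a pair in 1 library is a value with no test. No paired analysis was possible because there is a single group. Counting noise is largest in scarce genes: the SD of the log2 ratio was 0.77 (robust SD 0.52) at mean counts of 10 to 100, where counting alone gives 0.42, and 0.06 (robust SD 0.05) at 10000 or more, where counting alone gives 0.02, so depth does not account for all of the spread at either level.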

Other observations

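No hypothesis was tested here, and these genes were chosen after the data were seen. Of genes annotated as lincRNA, antisense, processed transcript, sense intronic, sense overlapping or bidirectional promoter RNA, 838 reached a TPM of 1 in both libraries. This class also holds processed-transcript models under symbols of protein-coding genes, such as Cct6a (351.2 ± 0.099 TPM), Tmem134 and Ptpmt1. Malat1, a nuclear RNA, stood at 5214 ± 149.7 TPM (SD, n = 2), H19, an imprinted RNA beside Igf2, at 730.01 ± 64.7 TPM, and Meg3, another imprinted RNA, at 217 ± 11.97 TPM. Hand2os1, which lies beside the cardiac factor gene Hand2, stood at 181 ± 0.474 TPM, Gas5 at 269 ± 0.297 TPM and Tug1 at 109 ± 0.156 TPM.

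Hox genes, which pattern the body axis, were scarce. Of 39 Hox genes, 2 reached a TPM of 1 in both libraries, Hoxb2 at 3.125 ± 0.035 TPM and Hoxd3 at 2.18 ± 0.354 TPM, and 34 stayed under 1 in both. Hoxa5 stood at 0.75 TPM in replicate 1 and 1.36 TPM in replicate 2.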
